A study of Homo sapiens with 6 samples.

How the data were processed

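The series held 6 one-colour arrays of U251 cells, an established human glioblastoma line. Per the labels, 3 arrays came from normal culture and 3 from methionine-deprived culture, each at 48 h, and each array was called a biological replicate. The labels gave no culture dates or passages, so p-values measured the spread between these arrays. Per the labels' protocols, total RNA was extracted with Trizol and the labelled cRNA was cleaned on RNeasy columns. Cy3 was the dye. The design text named an Arraystar array for human long noncoding RNA, made on Agilent's platform.

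The deposited scanner files came from Agilent Feature Extraction 11.0.1.1, per the file headers, and held one linear intensity per spot, already corrected for background by that software and not yet scaled between arrays. The authors also deposited a value table whose scale and normalization the labels did not state. It was set against the scanner files: each column kept the order of that array's scanner values (Spearman's rho 1 over 60495 probes). It matched quantile-normalized log2 intensities with r 1, so these values by the authors were taken as log2, with no centring per gene. The medians of its columns were 6.417 or 6.418. The table served only as an alternative.

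Each array had 62921 spots, of which 1439 were marked as controls. Spots marked as non-uniform or as population outliers were left out (87 to 599 per array), and no spot was saturated. Probes named Negative (60), ASSPINKEIN (102) and CUST (20) were not marked as controls in the files but were treated as such, because their names set them apart. The other 60546 probes entered. The authors' table left out the probes treated as controls, but it also held 0 of the 45 genes tested by name below. Results for those genes could therefore not be checked in the authors' values. The log2 intensity was averaged over the spots of a probe, and each array's 75th percentile over these probes was subtracted. A probe was kept if the scanner software called it well above background on all 3 arrays of at least 1 group, judged for a probe with several spots by at least a fraction of 0.5 of them. This kept 44678 probes, and 44594 with at least 2 values per group were tested. The flag was lenient here: it marked 38.3% to 76.7% of the Negative spots on an array. A probe well above background in only 1 group has only a bound on its fold.

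Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The package data.table (version 1.17.8) read the files, and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Gene lists were tested with camera (preset correlation 0.01) against the other named genes, for lists with at least 5 measured members. The procedure was tested on simulated data with the real probes' means and spread for this comparison, over 44594 probes. It recovered 2% of 50 probes changed by a log2 fold of 0.5, 42% at 1, 92% at 1.5 and 98% at 2, and 5.65% of its calls were unchanged probes. The simulated noise was independent between probes and held no slide effect and no shift that varied with signal. These shares therefore may not hold for the real arrays. The number of arrays limits the precision.

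The files do not pair 60496 of the probes with genes, and no probe table was used here, so these are given by ID and not by gene or class of RNA. Gene names came from RefSeq accessions in the scanner files for Agilent's 50 probes printed 10 times each. Of these, 49 matched a symbol in a RefSeq table of assembly GRCh38.p14, with 1 probe per gene, and 1 Ensembl transcript had no match. The array files used another build, so no coordinates are given. These 49 genes are a fixed set that Agilent places on its arrays, not a sample of all genes. Of 30 gene lists fixed in advance, 27 had no named member, among them the amino acid response, the methionine cycle and the lists of noncoding RNAs, and they are not analysed here. MAT2A, ASNS, DDIT3, TRIB3, GAS5, MALAT1 and NEAT1 are not analysed here for the same reason.

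The test, the scaling, the filters, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per direction, the genes with a symbol, an adjusted p under 0.05 and groups that did not overlap: up to 8 protein-coding genes and 5 long noncoding RNAs with the greatest log2 fold change, and up to 2 bounds. It also took, whether or not they passed, up to 4 measured members of each gene list with the smallest adjusted p (6 for the amino acid response and the methionine cycle). DTL, the last of the 5 measured G1/S genes by adjusted p, ATAD2, COL13A1 and the genes of the closing part lie outside this rule and were chosen after their values were seen. The other genes of the panel enter only the counts.

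The alternatives planned were quantile normalization, median centring, a percentile over detected probes, normexp, the authors' table of values, no filter or a stricter filter on dim probes, eBayes with trend and robust prior, blocks for replicate number and slide, treat with a minimum log2 fold change of 0.5, other gene set tests, and leaving out each array. Normexp was planned on mean signals, which the scanner files used here do not hold. It was run on median signals with an offset of 50. Cyclic loess, a filter at the 95th percentile of the Negative probes, slide column as a block and camera against all probes, with either correlation, were added after the data were seen. Comparing the mean of a gene's probes with its brightest probe was not run, since each named gene had 1 probe.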

Results

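RNA was profiled in U251 glioblastoma cells grown for 48 h either in normal culture or without methionine, the essential amino acid that also feeds the cell's pool of methyl donor. Each group had 3 arrays. Judged by the scan identifiers, normal replicate 1 lay on a different slide from the other 5 arrays, which shared 1 slide. By the array barcodes, all normal arrays lay in row 2 of their slide and all deprived arrays in row 1. Every difference between the groups is therefore also one between slide rows, and the 2 cannot be told apart. The 75th percentile of signal lay between 128.8 and 220.5 units on the 6 arrays. The share of probes well above background was 64.8% for normal replicate 1 and 73.9% to 81.0% for the other arrays. All values are log2 intensities relative to that percentile of each array, and differences are deprived minus normal. Gene names could be given for 49 probes, and 45 of these genes were measured well enough to test. CFTR, CD69, TCF7 and CPS1 were not.

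The comparison asks which transcripts change when glioblastoma cells lose methionine. LMO2, a LIM-domain adaptor of transcription complexes best known from blood formation, measured 3.17-fold higher in the deprived cells, at 0.34 ± 0.06 against -1.32 ± 0.15 (SD, n = 3 each). That fold is uncertain and may understate the change, since 15 of the 60 Negative probes, which target no transcript, had a higher normal mean than LMO2. CHAF1B, a subunit of the chromatin assembly factor that places histones on newly copied DNA, was 2.64-fold lower, at 1.31 ± 0.10 against 2.71 ± 0.30 (SD, n = 3 each). CCNA2, the cyclin A of S phase and mitotic entry, fell by 0.91 on the log2 scale (SE 0.14, n = 3 each), to 0.59 ± 0.06 (SD), and was 1.88-fold lower. In total 8 named genes passed the test, 1 higher and 7 lower. In each of them all 3 deprived arrays lay beyond all 3 normal arrays, as in all 570 probes that passed.

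The measured log2 difference of LMO2 was 1.67 (SE 0.14, limma with Benjamini-Hochberg adjusted p = 0.00409), and 0.96 with normexp and its offset of 50. That of CHAF1B was -1.40 (SE 0.18, limma adjusted p = 0.0133), and CCNA2 had a limma adjusted p of 0.0257. DSCC1, part of a clamp loader that helps sister chromatids cohere, had -0.99 (SE 0.15, limma adjusted p = 0.0259). WDHD1, which ties the replicative helicase to DNA polymerase alpha, had -0.87 (SE 0.15, limma adjusted p = 0.0354). SPDL1, which brings dynein to kinetochores, had -0.80 (SE 0.14, limma adjusted p = 0.0394). PLA2G4A, the cytosolic phospholipase that releases arachidonic acid, had -0.99 (SE 0.15, limma adjusted p = 0.0247). Its deprived mean was exceeded by 3 of the 60 Negative probes. UCHL5, a deubiquitinase of the proteasome, had -0.81 (SE 0.13, limma adjusted p = 0.0280).

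Quantile normalization ended the calls of DSCC1, WDHD1, SPDL1 and UCHL5, with limma adjusted p from 0.181 to 0.194, and left 4 of the 8, as did the percentile over detected probes. Normexp ended those of DSCC1, WDHD1, SPDL1, UCHL5 and CCNA2 (limma adjusted p from 0.0561 to 0.198). Cyclic loess ended 4 of the 8 calls, and eBayes with trend and robust prior ended 1. With no filter on dim probes LMO2 and CHAF1B were the 2 that passed, and with treat, against a minimum log2 fold change of 0.5, LMO2 was the only 1. With slide as a block LMO2, CHAF1B, PLA2G4A and DSCC1 passed along with ATAD2, 5 genes in all. Within the shared slide, without normal replicate 1, CCNA2 passed as well, 6 in all. The slide term absorbs normal replicate 1, so these 2 settings compare the groups over the same arrays and are not separate checks. With slide column as a block LMO2, CHAF1B and ATAD2 were the 3 that passed. Without normal replicate 2, or without normal replicate 3, LMO2 and CHAF1B were the 2 that passed, and without any 1 of deprived replicates 1, 2 and 3 LMO2 was the only 1. With replicate number as a block 0 named genes passed. The labels do not say whether a number marks a shared culture.

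**Figure D1:**
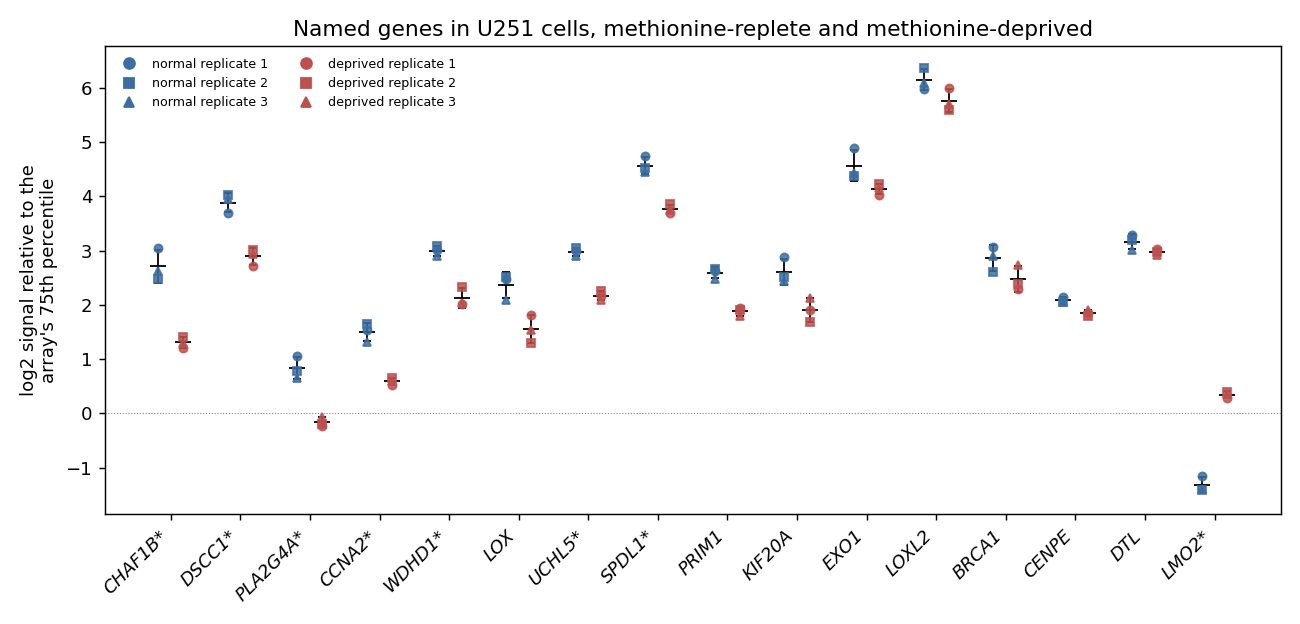
Log2 signal relative to each array's 75th percentile (y axis) for the named genes past the test, marked with an asterisk, and for the measured members of the gene lists (x axis). Each point is 1 array, and bars give the mean and SD of 3 arrays: the 3 deprived arrays of LMO2 lay above its normal arrays, and those of CHAF1B and CCNA2 below theirs.

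The list of G1/S and DNA replication genes had 5 measured members of 44. CHAF1B was lower over all probes tested, and CHAF1B and PRIM1 were the 2 that were lower adjusted over the list alone. PRIM1, the catalytic subunit of primase, had a log2 fold change of -0.71 (SE 0.13, limma adjusted p = 0.0510 over all probes). The other members did not pass either adjustment: EXO1, a repair exonuclease, had -0.43, BRCA1, of homologous recombination, had -0.38, and DTL, which marks the licensing factor CDT1 for degradation, had -0.19. The median of the 5 was -0.43, and it moved to -0.28 with slide as a block or without normal replicate 1, to -0.20 with quantile normalization or normexp, and to -0.22 with cyclic loess. As the 1 list large enough for a set test, its adjusted p equals its raw p. Set against the other named genes, limma's camera gave adjusted p = 0.290 with the preset correlation and adjusted p = 0.504 with an estimated correlation. The rotation test fry of limma, which asks whether the members move in a common direction, gave adjusted p = 0.00353. Against all probes tested, limma's camera gave adjusted p = 9.97e-06 with the preset correlation and adjusted p = 0.0429 with an estimated one, where the whole named panel had a median of -0.41 and all probes 0.057. DTL lay above 0 under quantile normalization (0.086), normexp (0.092) and cyclic loess (0.049).

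Of the G2/M and mitosis list 3 of 47 members were measured, too few for a set test. CCNA2 was lower over all probes tested, and CCNA2 and KIF20A, a kinesin of cell division, were the 2 that were lower adjusted over the list alone. KIF20A had a log2 fold change of -0.70 (SE 0.18, limma adjusted p = 0.129 over all probes). CENPE, a kinetochore kinesin, had -0.23 (SE 0.13, limma adjusted p = 0.465) and 0.016 under quantile normalization. Of the extracellular matrix list 2 of 29 members were measured. LOX, which cross-links collagen, had -0.81 (SE 0.19, limma adjusted p = 0.0974) and was the 1 member lower adjusted over the list alone. LOXL2, a related enzyme, had -0.39 (SE 0.17, limma adjusted p = 0.370).

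Over the named panel 36 of 45 genes lay below 0, with a median log2 fold change of -0.41. Adjusted over the 45 named genes alone, 21 were lower and 2 higher, LMO2 among them. ATAD2, a chromatin ATPase with a bromodomain, had -1.04 (SE 0.21, limma adjusted p = 0.0665 over all probes), and COL13A1, a transmembrane collagen, had -0.90 (SE 0.19, limma adjusted p = 0.0709). The groups did not overlap for 27 of the 45 genes (60%), against 21.2% of all probes tested, where chance gives 10%. Each named gene was averaged over 10 spots, unlike most probes tested, so the 2 shares are not directly comparable. Quantile normalization moved the median to -0.18, with 28 genes below 0, normexp to -0.17 and cyclic loess to -0.21, and without normal replicate 1 it was -0.40, with 38 below 0. As a sign of RNA quality, the log2 signal of the 3' control spot of GAPDH minus that of its 5' spot was 2.68 ± 0.08 in normal and 2.83 ± 0.06 in deprived arrays (SD, n = 3 each). For PGK1 it was 5.84 ± 0.21 and 5.39 ± 0.38 (SD, n = 3 each). An exact two-sided permutation test gave p = 0.1 for both, the smallest that 3 against 3 allows. The value was larger in deprived arrays for GAPDH and smaller for PGK1, so they give no single reading of RNA quality. The 5' spot of PGK1 had means of 0.40 in normal and 0.0008 in deprived arrays. The array's mouse PGK1 5' spot lay close by, at 0.14 and -0.02.

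Across the whole array 570 of 44594 probes passed the limma test, 162 higher and 408 lower in the deprived cells. All 570 had groups that did not overlap, as did 21.2% of the probes tested, where chance gives 10%. A change of at least 2-fold was met by 372 of them, 118 higher and 254 lower. For 17 probes that were higher and 17 that were lower, the dimmer group was not well above background on any array, so these have only a bound. Among probes well above background on all 6 arrays, ASHG19LNC1A100093133V5 measured 9.18-fold higher (log2 3.20, SE 0.17, limma adjusted p = 0.000944) and ASHG19AP1B100176476V5 measured 9.12-fold higher (log2 3.19, SE 0.16, limma adjusted p = 0.000944). ASHGV40049892V5 was 6.01-fold lower (log2 -2.59, SE 0.15, limma adjusted p = 0.000985) and ASHG19AP1B100042654V5 measured 5.65-fold lower (log2 -2.50, SE 0.23, limma adjusted p = 0.00640). For all of these but ASHGV40049892V5, 7 or 8 of the 60 Negative probes exceeded the mean of the dimmer group. Their measured folds are therefore uncertain and may understate the change. The files do not pair these IDs with genes.

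Higher probes made up 28.4% of the calls and lower probes 71.6%. Quantile normalization gave 41.1% higher and 58.9% lower among 555 calls, of which 418 were shared, the percentile over detected probes gave 40.7% and 59.3%, normexp with quantile 45.2% and 54.8%, cyclic loess 39.2% and 60.8%, and the values of the authors 39.4% and 60.6%. Treat turned the balance, with 21 higher and 19 lower among 40 calls. The count was 155 with no filter on dim probes, 956 with a filter at the 95th percentile of the Negative probes and 282 with slide column as a block. With replicate number as a block it was 14, with 8 higher and 6 lower. With slide as a block 391 probes passed, 137 higher and 254 lower, and within the shared slide, without normal replicate 1, 418 passed, 142 higher and 276 lower. Both settings compare the groups over the same arrays, so they are not separate checks. Leaving out any other single array of the 6 lowered the count by more than 1.5 times: the count was 177 without normal replicate 2, 249 without normal replicate 3, 186 without deprived replicate 1, 84 without deprived replicate 2 and 74 without deprived replicate 3.

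**Figure D2:**
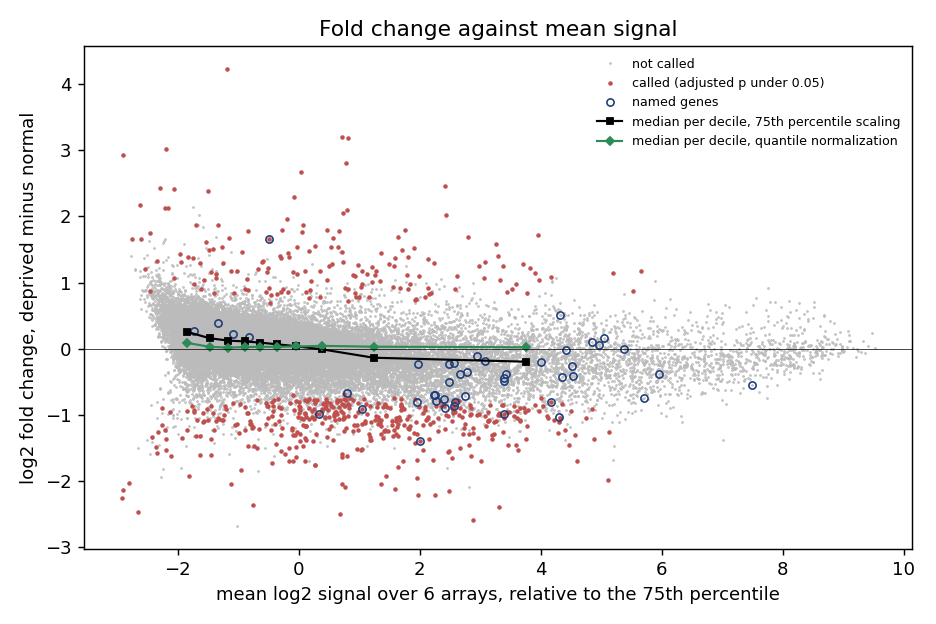
Log2 fold change, deprived minus normal (y axis), against the mean log2 signal over the 6 arrays relative to the 75th percentile (x axis). Each point is 1 probe, with the 570 called probes in red and the 45 named genes circled, and lines join the median of each decile of probes by mean signal under 2 scalings: under the 75th percentile the median went from 0.26 in the dimmest decile to -0.20 in the brightest, and under quantile normalization from 0.088 to 0.021.

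The array was designed around long noncoding RNA, and the files give the class of RNA for none of the IDs, so calls were compared between families of IDs instead. Among IDs that contain LNC, 169 of 19537 passed (0.865%), 64 higher and 105 lower. Among IDs that contain AP1B, 360 of 17509 passed (2.06%), 86 higher and 274 lower. Among IDs that contain V4, 33 of 7502 passed (0.440%), 11 higher and 22 lower. The odds of a call in the LNC family were 0.416 times those in the AP1B family (95% interval 0.344 to 0.501, Fisher's exact test, two-sided, p = 3.08e-22). Within deciles of mean signal the odds ratio was 0.513 (0.422 to 0.620, exact Mantel-Haenszel test, p = 6.96e-13). Both tests ran across probes, which are not independent. Among the 40 calls of treat the odds ratio was 0.683 and did not pass (Fisher's exact test, two-sided, p = 0.254).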

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

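Cyclic loess, normexp on median signals, the Negative-probe filter, the slide-column block and camera against all probes were chosen after the data were seen. Every setting run kept more lower than higher calls except treat and the replicate block. LMO2 and CHAF1B kept their direction in all 19 settings and passed in 18 and 14, at 0.96 to 1.75 and -1.52 to -1.04. Over the 16 genes that passed or belong to a list, 211 values under the alternatives kept direction and side of the threshold, 85 lost the call, 4 gained one and 4 reversed. DTL reversed under quantile normalization (0.086), normexp (0.092) and cyclic loess (0.049), and CENPE under quantile normalization (0.016). The cause was not tested, unless stated. Signal over background limits the dim probes, since the filter decides how many are tested.

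Against 570 calls (162 higher, 408 lower, 372 at least 2-fold, 8 named genes), no filter gave 155 (64, 91, 155, 2) over more probes, and the 95th percentile of Negative probes gave 956 with 755 lower and 14 named over fewer. Slide column as a block gave 282 with 160 lower and 3 named over 4 arrays, and treat gave 40 (21, 19) with 1 named. The lower calls were 252 with a percentile over detected probes, 228 with normexp (121 at least 2-fold) and 254 with slide as a block. The higher calls were 269 in the authors' table and 261 with cyclic loess. Named calls were 4 with quantile normalization, 4 with that percentile, 4 with normexp, 13 for probes well above background on all 6 arrays, 5 with slide as a block and 5 with cyclic loess. Leaving out 1 array gave 74 to 418 calls, 32 to 142 higher, 39 to 276 lower, 74 to 296 at least 2-fold and 1 to 6 named genes, with fewer arrays to estimate the spread. The LNC to AP1B odds ratio was 0.683 under treat (p = 0.254, Fisher's exact test). The G1/S median of -0.43 passed with limma's fry (adjusted p = 0.00353) and camera against all probes (adjusted p = 9.97e-06, preset correlation, and adjusted p = 0.0429, estimated). With an estimated correlation, limma's camera against the other named genes gave adjusted p = 0.504. That median was -0.28 with slide as a block, -0.20 with quantile normalization or normexp, -0.22 with cyclic loess and -0.52 to -0.28 with 1 array left out.

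Whether the replicate numbers pair the arrays was not settled. Same-numbered arrays deviated with r -0.11, -0.16 and 0.05 across probes, and no array correlated best with its own number. Deviations shared within a slide column could mask a pairing, so these values cannot exclude one. With the replicate block the fit called 14 probes, 8 higher and 6 lower, all 14 at least 2-fold, and 0 named genes (5476 probes had an unadjusted limma p under 0.05). The LNC to AP1B odds ratio was 0.399 (p = 0.164, Fisher's exact test).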

Other observations

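Further genes of the named panel, chosen after their values were seen, did not pass the test over all probes. CENPQ, of the inner kinetochore, had a log2 fold change of -0.76 (SE 0.15, limma adjusted p = 0.0595), and ITGB3BP, another protein of that complex, had -0.51 (SE 0.15, limma adjusted p = 0.196). ABRAXAS1, which scaffolds a BRCA1 complex, had -0.66 (SE 0.13, limma adjusted p = 0.0533). RAD54B, of homologous recombination, had -0.44, the helicase WRN -0.36 and SMC6, of a repair complex related to cohesin, -0.23. The chromatin proteins BAZ1A, SMARCAD1 and ZZZ3 had -0.20, -0.11 and 0.16.

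EIF5B, a translation initiation factor, had -0.71 (SE 0.18, limma adjusted p = 0.133), and NOC3L, of ribosome assembly, had -0.01 with a 95% interval from -0.31 to 0.30. SPP1, which encodes osteopontin, had -0.55 (SE 0.18, limma adjusted p = 0.237). Control spots for the housekeeping genes GAPDH and PGK1 lay lower in deprived cells too. The 3' spot of PGK1 was at 6.26 ± 0.14 in normal and 5.39 ± 0.19 in deprived arrays, and that of GAPDH at 7.69 ± 0.17 and 7.27 ± 0.15 (SD, n = 3 each, exact two-sided permutation p = 0.1 for both, the smallest possible). Over 5 scalings the 3' and 5' spots of both genes kept a difference below 0, from -0.89 to -0.31.

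The background test, the slide row test, the tests of the dimmest and brightest deciles taken singly, and the matched sets under quantile normalization were chosen after the data were seen.

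Named genes lay lower on balance, with a median of -0.41 over 45 genes. To weigh a scaling that shifts bright probes down, 10000 sets of unnamed probes matched on mean signal were drawn. They had medians of -0.30 to -0.04 (central 95%), and 0.02% of sets were as low as the panel. Each set drew its probes independently, while camera estimated a correlation of 0.34 among the measured G1/S genes. The range may therefore be too narrow for this panel. The panel lay below the matched sets, but the test cannot exclude scaling as the whole source. Under quantile normalization the panel's median was -0.18 against -0.09 to 0.13 for matched sets, with the same limit. Without the array on the separate slide the panel's median was -0.40 against -0.30 to -0.08. The median thus hardly moved, which argues against that array as the whole source. Position on the slide stays open, since 0 arrays lay in a slide row that held the other group, and row and culture cannot be told apart. An effect of methionine deprivation itself also stays open: the 5 measured G1/S genes, with a median of -0.43, were not set apart from the rest of the panel (limma camera adjusted p = 0.290, and adjusted p = 0.504 with an estimated correlation), which holds other genes of the cell cycle as well.

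Dim probes shifted up and bright probes down, with medians of 0.26 in the dimmest and -0.20 in the brightest decile, a gap of 0.45, while quantile normalization gave 0.088 and 0.021. The dim part may come from the normal array on the separate slide: without it the dimmest decile had a median of 0.070, yet the gap stayed at 0.28, which argues against that array as the source of the whole pattern. A background that differed between groups stays open: the Negative probes, themselves dim, were higher by a median of 0.21 in deprived arrays (46 of 60 probes), but exact two-sided permutation tests over the 6 arrays gave p = 0.3 for medians of probe means and p = 0.1, the smallest possible, for medians of spots. Within the shared slide the Negative probes differed by 0.025, while the brightest decile kept a median of -0.21. A change of abundant transcripts with methionine deprivation also stays open and was not tested.

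For the count of 570 calls, the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the only 1 with as many calls, and the highest of the others had 0. At an unadjusted limma p under 0.05 the real split had 6108 probes. The split of normal replicates 1 and 2 with deprived replicate 1 against the rest had 4713.

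Some arrays deviated alike across groups. Normal replicate 2 and deprived replicate 1, both in column 1, deviated from their group means with r 0.27 across probes, and normal replicate 3 and deprived replicate 2, both in column 2, with r 0.13. Normal replicate 1 and deprived replicate 3, on different slides and in different columns, had r 0.12. Because deviations were taken from group means, that value is tied to those of the other arrays and is not a separate observation. Within column 1 the named genes had a median difference of -0.33 and 38 of 45 lay lower, and within column 2 it was -0.40 and 33 of 44 lay lower. Normal replicates 2 and 3 correlated across probes with r 0.982, and each with normal replicate 1 at r 0.963 and 0.968.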
